A study of Homo sapiens with 40 samples.

How the data were processed

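H3K27me3, a histone modification laid down by Polycomb repressive complexes, was profiled by CUT&Tag, in which an antibody tethers a transposase to chromatin so that DNA around the modification is cut and sequenced. The cells were KMS-11, a human multiple myeloma line that carries the t(4;14) translocation, through which the histone methyltransferase gene NSD2 is overexpressed. Each library started from 50000 nuclei and was amplified for 13 PCR cycles, per the labels' protocols. The peak lists of 30 H3K27me3 libraries, 15 groups of 2, were used. A further 10 libraries in the labels (2 with IgG, 4 for H3K27ac and 4 for H3K4me3) were not analysed here.

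The groups were the parental line of the knockout (KO) experiment, NSD2 KO clones 3 and 12, and, at days 0, 7, 14 and 21 of the compound dTAGV-1, the parental line used for dTAG engineering and NSD2-dTAG clones 8 and 11. dTAGV-1 recruits the VHL ubiquitin ligase to a protein that carries the dTAG domain, which leads to its degradation. The labels' protocols give 100 nM for the NSD2-dTAG cells and do not state a dose for the parental line. The series text calls the replicates of the KO and dTAG clones biological. No label names separate cultures for the parental libraries, so p-values that rest on those measure the spread between libraries, which may be technical. Day 0, 7, 14 and 21 libraries of a clone are not independent clones.

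Reads were processed by the authors with fastp 0.24.0, Bowtie2, SAMtools, Picard, deepTools 3.5.1, MACS3 3.0.2, DESeq2 and ChIPseeker 1.42.1 against hg38, per the submitters' processing notes, which give no roles or order. The deposited lists are in the broadPeak format, 1 for each library and no pooled list. Whether the IgG libraries served as control, and the calling options, are not given in the sources used here. In the deposited lists, the score of a peak is its -log10 q times 10, cut to a whole number. The fold column of the deposited lists holds a ratio, the enrichment of the peak over the caller's background. The authors' lists also give -log10 p and -log10 q for each peak, and the lowest -log10 q in the lists lay between 1.00 and 1.01. These values belong to single peaks and were used only to filter or rank peaks within a list and to solve the caller's background.

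Depth was not listed. It was estimated, after the data had been seen, as the genome-wide background pileup (fragments per position) of the caller. Fold and p of each of the shortest 2% of peaks were solved for a whole pileup and a background, with a tolerance of 0.002 in -log10 p, and the commonest background within a window of 0.01 was taken. This assumes that the caller added a pseudocount of 1 to pileup and background, and that a genome-wide background applied to these peaks. A local or IgG background would break the solution where it applied, and read counts were not at hand to check it, so every pileup value rests on these assumptions. Between 63 and 289 peaks per library gave a solution. The commonest value held 26 to 142 of them, and the next best separate value 1 to 19. The estimate ran from 0.922 to 3.26 across the libraries. Called length rises with depth, so deeper libraries give longer lists, and a region that is not listed in a shallow library can still carry the mark.

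Peaks of a library were merged, and their summed length on chromosomes 1 to 22 and X is its called length. A gene was scored by the percent of its annotated bases inside a peak. Gene positions came from RefSeq on GRCh38.p14, the same assembly as hg38, for 19451 protein-coding genes of at least 1 kb. The annotation has no strand, so promoter windows could not be placed. Genes with a mean covered share between 1% and 99% over the 30 libraries entered the test (13977 genes). The test was limma 3.58.1 in R 4.3.3, with 1 mean per group over all 30 libraries (15 residual degrees of freedom), eBayes with a trend on the mean, and Benjamini-Hochberg adjusted p under 0.05. Gained means a higher covered percent and lost a lower one. Windows (bins) of 25 kb were treated the same way. Every adjusted p of a gene below comes from limma. For each gene it rests on the spread between the 2 libraries of a group, pooled over the 15 groups. It does not measure the spread between clones. Groups without coverage add no spread, so it can be too small for genes whose KO or treated libraries vary. KRTAP26-1, for example, was 18.0% ± 22.6 covered in the KO clones (SD, n = 4), with adjusted p = 0.000688.

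Called lengths and bin coverages were compared by exact two-sided permutation tests of the difference in means. The pooled comparison of 16 against 14 libraries used 100000 two-sided permutations within the KO and dTAG experiments. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and data.table (version 1.17.8) were used. Gene groups comprised 22 lists, tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry. They were HOX cluster genes, developmental transcription factors, genes tied to t(4;14) or NSD2, plasma cell, B cell, T and NK cell, myeloid, neuronal, and epithelial and mesenchymal genes, antigen presentation and interferon genes, PRC2, PRC1 and NSD family genes, cell cycle inhibitors and tumour suppressors, housekeeping genes, clustered protocadherins, other cadherins, olfactory receptors, keratins, zinc finger (ZNF) genes, ribosomal protein genes, collagens, potassium channels, and glutamate and GABA receptors. The comparisons, tests, lists and most alternatives were fixed before the data were examined.

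The genes named were also set by a rule fixed then. For the KO clones and for day 21 of the dTAG clones, it took the 10 largest gains and the 10 largest losses among genes of at least 10 kb past the threshold, where every KO or treated library lay beyond every control library, with at most 1 gene per Mb. It also took up to 4 members of each list past the threshold, and NSD2, FGFR3 and CCND2 whatever their values. Names outside this rule are marked as chosen after their values were seen.

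The gene test was tested on simulated data made for the KO comparison over the 13977 genes, with 50 genes raised by each of 4 sizes. It recovered 34% of genes raised by 0.05 in covered fraction, 58% at 0.1, 80% at 0.2 and 92% at 0.4, and called 18 of 13777 unchanged genes. With unchanged genes and noise shared within libraries, 15 of 50 draws gave any call, with at most 8 genes. In the first simulation the 18 false calls stood beside 17, 29, 40 and 46 true ones. Both results exceed the rate of 0.05 at which the threshold aims, so gene calls may hold more false ones than that. The exact test on 4 against 4 simulated libraries passed in 3.0% of 1000 draws without a difference.

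Alternatives covered stricter peak lists (-log10 q of at least 5, or fold of at least 4), peaks joined over gaps of up to 3 kb, lists shortened to the same total length by -log10 p, covered percent scaled by called length, an arcsine square root, no gene filter, no trend, only the compared groups, changes of at least 20 percentage points, other bin sizes (10 and 100 kb), all sequences in the lists, log2 length and each library left out. Background pileup as a covariate or divisor was added after the data had been seen. Scaling assumes that every library holds the same total of the mark, and the unscaled values assume equal sensitivity of the lists. The median change over all tested genes was 1.46 percentage points in the KO comparison, 0.634 with the pileup covariate and -1.31 after scaling. For dTAG clones at day 21 these medians were 2.05, 0.443 and -1.34, so a loss after scaling is a loss relative to the total.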

Results

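The series asked how the genomic spread of H3K27me3 changes when NSD2, a methyltransferase that deposits H3K36me2, is lost from t(4;14) myeloma cells. The data were H3K27me3 peak lists of 30 CUT&Tag libraries, 2 for each of 15 groups. The lists held 34740 to 205920 peaks on chromosomes 1 to 22 and X. They covered 36.1 to 168 Mb, with a median peak width of 553 to 827 bp. Estimated background pileup, which stands for depth, was 0.922 to 3.26 fragments per position. Where 2 replicates of a group were compared, 43.4% to 90.0% of the peaks of either list overlapped a peak of the other by at least 1 bp.

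NSD2 (chromosome 4, 1871393 to 1982192, hg38) lay almost wholly outside peaks. At most 0.975% of the gene was covered in any library, and 11 of 30 libraries had any coverage. CCND2, a cyclin gene on chromosome 12 (4273762 to 4305353), was covered by at most 3.17%, with 8 of 30 libraries above 0. Neither gene reached the 1% mean needed for a test. FGFR3, the receptor gene beside NSD2 that the translocation also activates (chromosome 4, 1793293 to 1808867), was covered by 2.57% to 55.3%. FGFR3 was 30.0% ± 7.88 covered in the KO clones (SD, n = 4) and 22.6% ± 12.7 in the KO parental line (SD, n = 2), adjusted p = 0.821. At day 21 it was 29.3% ± 17.2 in the dTAG clones against 21.0% ± 16.1 at day 0 (SD, n = 4 each), adjusted p = 0.655. The direction of both FGFR3 differences depended on the scale. After scaling by called length they were -7.34 (KO) and -14.3 (day 21) percentage points. With the pileup covariate they were -2.86 and -15.4, and none of these was called. Peak lists cannot show whether NSD2 protein was lost, so the labels were not checked in this way.

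The KO comparison asked where H3K27me3 differs in cells that never recover NSD2. The genes with the largest gains included a protease, a water channel, an immune receptor and a nuclear receptor gene. CTSK, the bone-resorbing protease cathepsin K (chromosome 1, 150796208 to 150808260), was outside peaks in both parental libraries and 28.6% ± 9.52 covered in the KO clones (SD, n = 4; adjusted p = 0.00329). AQP4, the astrocyte water channel (chromosome 18, 26852038 to 26865803), went from 0% to 22.7% ± 3.61 (adjusted p = 1.3e-08). SLAMF8, an immune receptor gene (chromosome 1, 159826873 to 159837492), went from 11.6% ± 8.43 to 39.4% ± 10.9 (adjusted p = 0.0155), and NR2F1, a nuclear receptor of neural development (chromosome 5, 93583222 to 93594611), from 4.27% ± 0.739 to 27.4% ± 2.56 (adjusted p = 0.00547). The other genes with the largest gains were TEX35 (23.6 percentage points), PGLYRP3 (22.7), LRRC52 (22.4), MS4A18 (22.1), SOX10 (21.5) and ADCY6 (21.2), with adjusted p of 0.00108 to 0.041. After scaling by called length SLAMF8, NR2F1, PGLYRP3, SOX10 and ADCY6 kept their direction but had adjusted p over 0.05, as did PGLYRP3 and SOX10 with the pileup covariate.

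Coverage fell in far fewer genes before scaling by called length, after which lost genes were the larger group. CBARP, a calcium channel regulator (chromosome 19, 1228287 to 1238502), fell by 36.6 percentage points, from 61.2% ± 6.10 (SD, n = 2) to 24.5% ± 5.94 (SD, n = 4; adjusted p = 0.0238). ZSCAN10, a zinc finger factor of stem cells (chromosome 16, 3088890 to 3099294), fell from 41.5% ± 1.18 to 22.6% ± 1.94 (adjusted p = 0.00337). OPN1LW, the red cone opsin on chromosome X (154144243 to 154159032), fell from 17.8% ± 5.80 to 3.34% ± 2.82 (adjusted p = 0.000165). OPN1LW has near-identical neighbours, so its reads may be shared. The other large losses were BAIAP3 (-19.7 percentage points), ATG101 (-13.8), MYDGF (-11.8), TMEM61 (-11.7), FCGRT (-11.0), PDZD7 (-11.0) and PSG3 (-9.98), with adjusted p of 0.000401 to 0.0499. At a fold of at least 4, BAIAP3 KO vs parental turned to 3.19 and ATG101 KO vs parental to 5.96, and PDZD7 lost its call after scaling (adjusted p = 0.064).

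Across 13977 genes, limma called 2510 gained and 104 lost in the KO clones at adjusted p under 0.05. The counts of genes gained KO vs parental and genes lost KO vs parental depended on the scale. After scaling by called length they were 1608 and 1893, and with the lists shortened to equal length 254 and 237. With pileup as covariate they were 2390 and 391, and 2338 gained and 102 lost genes were called both with and without that covariate. With only the compared groups in the fit they were 754 and 44. Without KO parental replicate 1 or 2 the gained count was 1512 or 1078. With peaks at -log10 q of at least 5 limma called 0 genes.

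Called length in the KO clones was 130 Mb ± 30.7 (SD, n = 4), against 67.4 Mb ± 19.3 in the parental line (SD, n = 2), a ratio of 1.94. The exact two-sided permutation test gave p = 0.133 (adjusted p = 0.16 over 6 length comparisons), and the design cannot go below 0.0667. Clone 3 had 168 and 137 Mb, and clone 12 had 123 and 94.0 Mb, against 81.0 and 53.7 Mb in the parental line. Mean background pileup in the KO clones was 1.22 times that of the parental line. Per unit of pileup the ratio of length was 1.55 (exact two-sided permutation p = 0.0667, adjusted p = 0.106 over 54 tests). Length in peaks at -log10 q of at least 5 was not higher. It was 21.1 Mb ± 7.66 in the KO clones and 23.7 Mb ± 17.7 in the parental line (SD, n = 4 and 2). Of the parental peaks, 80.3% on average overlapped a peak of a KO library by at least 1 bp, while 33.4% of the KO peaks overlapped a parental one. With a reciprocal overlap of at least 50% these shares were 51.7% and 20.9%. The 2 KO clones are the units of the genotype, so 4 libraries overstate the replication.

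**Figure D1:**
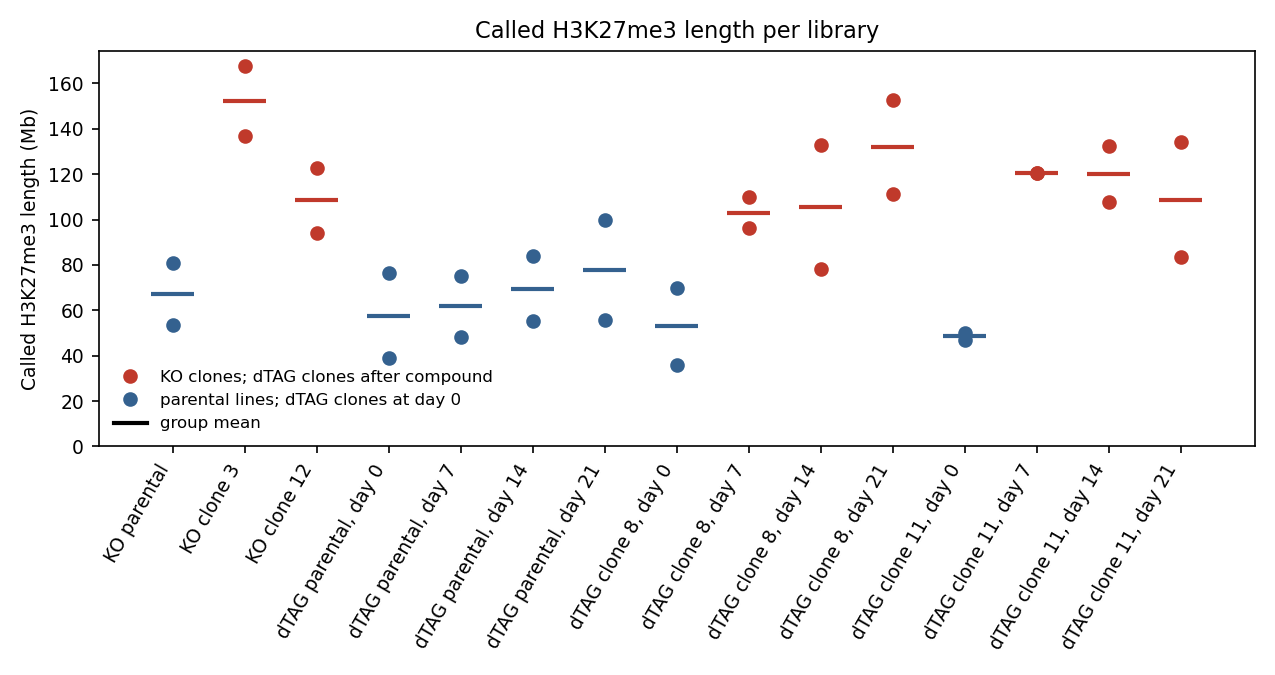
Called H3K27me3 length in Mb for each of the 30 libraries (points) with the mean of each group (bars), red for KO clones and compound-treated dTAG clones and blue for parental lines and day 0 clones. The 12 treated dTAG clone libraries lie between 78.3 and 153 Mb and the day 0 clone libraries between 36.1 and 69.9 Mb.

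Regions without genes took up a large part of the KO gain. Of 49812 tested bins of 25 kb, limma called 18575 gained and 260 lost. With lists shortened to equal total length these were 873 and 671, at -log10 q of at least 5 they were 3 and 11, at a fold of at least 4 they were 17 and 9, and with peaks joined over gaps up to 3 kb they were 11197 and 121. Without KO parental replicate 1 or 2 they were 8947 and 105, or 7190 and 320. Among bins without a protein-coding gene 48.1% were gained (9139 of 19011), among bins wholly inside genes 40.5% (5413 of 13370) and among bins partly inside genes 23.1% (4023 of 17431). Chromosome 18 (59.1%) and chromosome 4 (53.0%) had the highest shares of gained bins, and chromosomes 19 (2.76%) and 22 (9.62%) the lowest. Chromosome 19 had the most genes per Mb (24.5). Chromosome 22 had 8.72, fewer than chromosomes 16 (9.25) and 11 (8.94), of whose bins 23.6% and 31.3% were gained. Genes held 45.5% ± 1.40 of the called length in the KO clones (SD, n = 4) and 51.8% ± 0.103 in the parental line (SD, n = 2). This exact two-sided permutation p was 0.0667, the smallest possible (adjusted p = 0.106 over 54 secondary tests). Called length outside genes was 71.3 Mb ± 18.3 and 32.5 Mb on average, and inside genes 59.0 Mb ± 12.4 and 34.9 Mb.

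The dTAG comparison asked how H3K27me3 changes over time once NSD2 is degraded. The genes with the largest gains at day 21 included a muscle, a lipid droplet and an immune receptor gene. MYBPHL, a myosin-binding protein gene of heart muscle (chromosome 1, 109292365 to 109307011), went from 2.90% ± 3.31 at day 0 to 40.5% ± 14.0 at day 21 (SD, n = 4 each; adjusted p = 0.00106). CIDEC, a lipid droplet protein of fat cells (chromosome 3, 9866710 to 9880253), went from 0.439% ± 0.879 to 26.2% ± 8.82 (adjusted p = 0.000178). CTSK went from 2.62% ± 5.24 to 33.2% ± 4.76 (adjusted p = 0.00029) and SLAMF8 from 8.06% ± 6.93 to 39.7% ± 11.4 (adjusted p = 0.00112). The other largest gains were HPCAL4 (32.2 percentage points), C1orf116 (30.0), FCRL3 (28.9), SYNPO2L (27.6), INHBC (26.2) and ISM2 (26.1), with adjusted p of 4.33e-05 to 0.00236. After scaling HPCAL4 and C1orf116 kept their direction but had adjusted p over 0.05. ISM2 dTAG clones day 21 vs day 0 turned to -0.608 with lists shortened to equal length and to -1.06 at -log10 q of at least 5, and FCRL3 dTAG clones day 21 vs day 0 to -1.45 at a fold of at least 4.

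Losses at day 21 were again far fewer than gains before scaling by called length (69 and 3697), but not after it (4413 and 2250). TEKTL1, a gene on chromosome 19 (15010726 to 15023276), fell by 24.7 percentage points, from 36.8% ± 6.48 to 12.0% ± 11.0 (SD, n = 4 each; adjusted p = 0.00572). CCR7, the lymph node homing receptor (chromosome 17, 40553769 to 40565472), fell from 65.5% ± 7.99 to 44.3% ± 5.99 (adjusted p = 0.007). ZNF354C, a zinc finger gene on chromosome 5 (179060373 to 179083977), fell from 19.1% ± 8.12 to 0% in all 4 libraries (adjusted p = 0.000715). CNN2 (-15.0 percentage points), FPR3 (-9.66), SLC31A2 (-8.01), PCYT2 (-7.75), RCN3 (-6.61), TBX5 (-5.14) and BAD (-5.13) followed, with adjusted p of 9.87e-05 to 0.0401. With the pileup covariate PCYT2 (adjusted p = 0.0588) and BAD (adjusted p = 0.0762) lost their calls.

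The number of genes was already high at the earliest time. limma called 2951 gained and 34 lost at day 7, 3079 and 88 at day 14, and 3697 and 69 at day 21. These are the genes gained dTAG clones day 7 vs day 0, genes lost dTAG clones day 7 vs day 0, and likewise genes gained dTAG clones day 14 vs day 0, genes lost dTAG clones day 14 vs day 0, genes gained dTAG clones day 21 vs day 0 and genes lost dTAG clones day 21 vs day 0. Scaled by called length the splits were 2023 and 4055, 2257 and 4473, and 2250 and 4413. With the lists shortened to equal length they were 249 and 273, 456 and 525, and 550 and 527. With the pileup covariate they were 1331 and 353, 1951 and 854, and 2053 and 712. With peaks at -log10 q of at least 5, 28 genes were gained and 9 lost at day 21.

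Single libraries moved some counts by over 1.5 times. The count of genes gained dTAG clones day 7 vs day 0 was 1675 without clone 8 day 0 replicate 2, 1907 without clone 11 day 0 replicate 2 and 1847 without clone 8 day 7 replicate 2, and that of genes gained dTAG clones day 14 vs day 0 was 1941 without clone 8 day 14 replicate 1. Lost genes without clone 8 day 0 replicate 2 numbered 64 at day 7, 148 at day 14 and 117 at day 21. Lost genes at day 7 numbered 20 without clone 8 day 7 replicate 2, and 16 or 19 without clone 11 day 7 replicate 1 or 2. At day 14 they numbered 58 without clone 11 day 14 replicate 1. At day 21 they numbered 40 without clone 8 day 21 replicate 1 and 39 without clone 11 day 21 replicate 2.

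Called length in the clones was 50.7 Mb ± 14.1 at day 0, 112 Mb ± 11.6 at day 7, 113 Mb ± 25.9 at day 14 and 120 Mb ± 29.9 at day 21 (SD, n = 4 each). The ratios to day 0 were 2.20, 2.22 and 2.37. Mean background pileup was also higher, at 1.53, 1.49 and 1.62 times that of day 0. Per unit of pileup, a measure chosen after the data were seen, the ratios of length were 1.40, 1.43 and 1.41. There each exact two-sided permutation p was 0.0286, with adjusted p = 0.0671 over 54 tests. Each exact two-sided permutation test gave p = 0.0286, the smallest possible with 4 against 4 libraries (adjusted p = 0.0429 over 6 comparisons), and all 4 treated libraries were above all 4 day 0 libraries. Without any 1 of the 4 day 0 libraries (clone 8 or 11, replicate 1 or 2) the p was 0.0571 at days 14 and 21 and stayed at 0.0286 at day 7. Length in peaks at -log10 q of at least 5 did not follow. It was 18.4 Mb ± 11.3 at day 0, 21.8 Mb ± 3.71 at day 7, 17.0 Mb ± 8.42 at day 14 and 20.9 Mb ± 10.6 at day 21.

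The untagged parental line served as a control for the compound. In that line 2 genes gained coverage at day 21 and none lost it. They were USP7, a deubiquitinase (chromosome 16, 8892097 to 8963906; 3.93 percentage points, adjusted p = 0.0109), and TMEM216, a cilium gene (chromosome 11, 61392587 to 61398846; 11.3 percentage points, adjusted p = 0.0225), both named after their values were seen. limma called 0 genes at day 7 (292 at unadjusted p under 0.05) and 0 at day 14 (349), and at day 21 unadjusted p was under 0.05 for 536 genes. Scaling gave 6 gained and 4 lost at day 21. With 2 against 2 libraries, a change of the same size was harder to call here than in the clones, so the counts are not comparable. The median change over all tested genes at day 21 was 0.848 percentage points in this line and 2.05 in the clones. The mean changes were 2.22 and 3.90. In this line the median was -0.0194 with the pileup covariate and 0 after scaling. The gained count at day 21 was 64 without day 21 replicate 2, 10 without day 21 replicate 1 and 0 without day 0 replicate 2, and the lost count was 6 without day 0 replicate 2 and 1 without day 0 replicate 1. Called length was 57.6 Mb ± 26.4 at day 0 and 77.8 Mb ± 31.2 at day 21 (SD, n = 2 each). The exact two-sided permutation p was 0.667, and 0.333 is the smallest possible (adjusted p = 0.667). Without day 21 replicate 1, the day 21 library was below the day 0 mean, with a difference of -1.87 Mb. Replicates 1 and 2 had 75.3 and 48.2 Mb at day 7 and 83.8 and 55.2 Mb at day 14.

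The test of the difference between the clones' change and the parental line's change called 270 genes higher and 12 lower at day 21, and 673 and 771 after scaling. The interaction was 25.4 percentage points for CTSK (adjusted p = 0.137). Without dTAG parental day 0 replicate 1 the test called 5 higher and 3 lower. Without the other parental libraries the higher count was 27 (day 0 replicate 2), 24 (day 21 replicate 1) and 28 (day 21 replicate 2), with 0, 8 and 50 lower. Leaving out clone 8 gave 98 and 85 higher (day 0 replicates 1 and 2) and 132 and 738 (day 21 replicates 1 and 2). Leaving out clone 11 gave 85 and 77 (day 0) and 147 and 848 (day 21), so the count of 270 rests on single libraries. The lower count was 7 without day 21 replicate 1 of clone 8 or of clone 11, and 21 without clone 11 day 21 replicate 2.

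Both ways of removing NSD2 were then compared. Each change was a difference of means from separate libraries. The filter of 1% to 99% and each gene's estimate of spread came from all 30 libraries, so the calls were not independent. Of the 2510 genes gained in the KO clones, 1877 were also gained at day 21 in the dTAG clones, against 664 if the lists were independent. Of the 104 genes lost in the KO clones, 10 were also lost at day 21, against 0.513. These expected counts ignore the shared filter and spread, so part of the excess may come from them. CDX2, the intestinal homeobox factor (chromosome 13, 27960918 to 27969315), fell in both, from 33.3% ± 5.15 (SD, n = 2) to 7.94% ± 7.08 (SD, n = 4) in the KO comparison (adjusted p = 0.000682) and from 27.7% ± 3.64 to 10.5% ± 7.27 at day 21 (SD, n = 4 each; adjusted p = 0.00181). Not every gene was shared. AQP4 changed by 1.17 percentage points at day 21 (adjusted p = 0.512) and HPCAL4 by -2.41 in the KO clones (adjusted p = 0.879). None of the 10 largest KO losses named above was called lost at day 21. There CBARP changed by -14.9 (adjusted p = 0.247), ZSCAN10 by -1.88 (adjusted p = 0.755) and OPN1LW by -1.15 (adjusted p = 0.702). TMEM61, lost in the KO clones, was called gained at day 21 (8.23, adjusted p = 0.0381). Changes correlated across genes with r = 0.54, or 0.62 with the pileup covariate. Genes are not independent replicates.

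Bins gained in the KO clones also became covered when NSD2 was degraded. The treated dTAG clone libraries scored here had a part in choosing these bins. Bins entered the test by their mean coverage over all libraries, and the spread of each bin also came from all groups. This can favour bins that are covered in treated dTAG clones. The rise and its p are therefore not independent of the choice of bins. The 18575 bins were 0.834% ± 0.288 covered on average in the dTAG clones at day 0, 7.20% ± 1.03 at day 7, 7.87% ± 1.94 at day 14 and 8.37% ± 2.20 at day 21 (SD, n = 4 each), 10.0-fold at day 21. With lists shortened to equal total length, the 873 bins then called gained went from 1.48% ± 0.239 at day 0 to 4.90% ± 0.264 at day 21 (SD, n = 4 each), which is 3.31-fold. The fold change was 5.93 with bins of 100 kb, 16.3 with bins of 10 kb, 2.28 in the 17 bins at a fold of at least 4, 56.3 in the 3 bins at -log10 q of at least 5, and 19.5 without KO parental replicate 2, so its size depends on these choices. In the dTAG parental line they were 1.11% ± 0.711, 1.36% ± 0.586, 1.47% ± 0.740 and 1.89% ± 0.977 covered at the same times (SD, n = 2 each). The exact two-sided permutation test of day 21 against day 0 in the clones gave p = 0.0286, the smallest possible, with all 4 treated libraries above all 4 day 0 libraries. The 260 bins lost in the KO clones were 4.33% ± 0.807 covered at day 21 and 5.04% ± 1.45 at day 0 (SD, n = 4 each; exact permutation p = 0.514). They were 14.1% and 11.2% covered in the KO parental libraries, which had a part in choosing them, and 4.08% to 5.80% in the KO clones. Day 0 dTAG clones had 3.88% to 7.16% and dTAG parental libraries 4.68% to 9.66%. Coverage as low as in the KO clones thus also occurred where NSD2 was retained, without regard to depth.

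**Figure D2:**
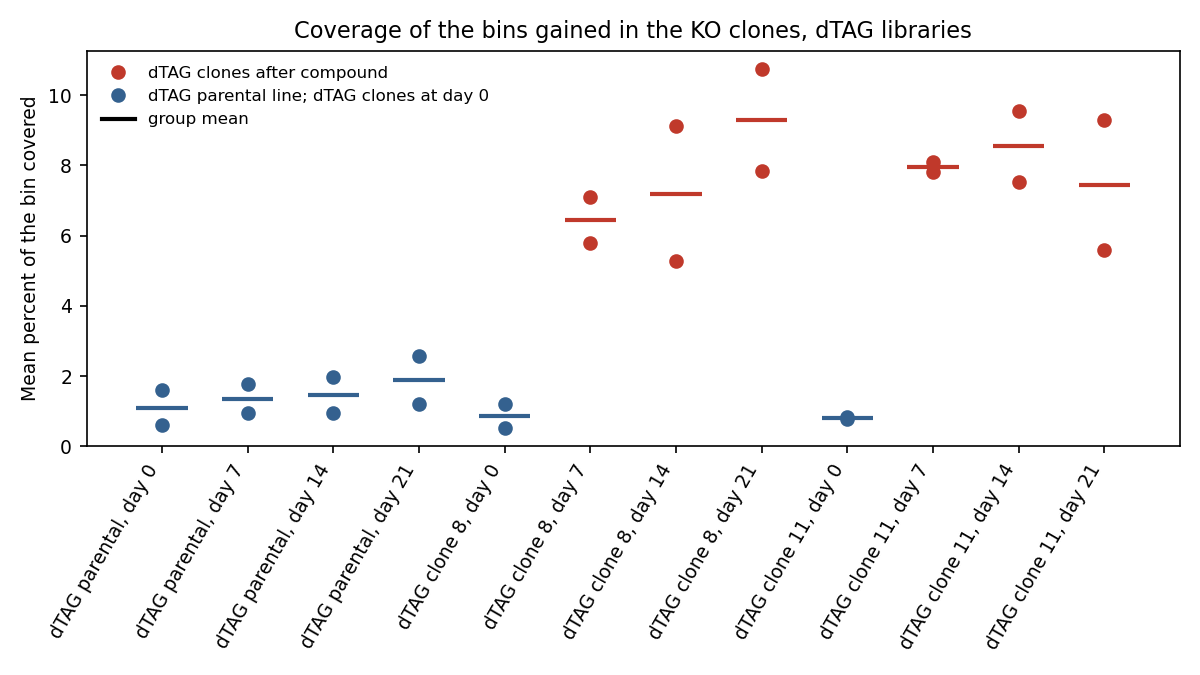
Mean percent of the 18575 KO-gained bins of 25 kb that is covered in each dTAG library (points) with group means (bars), red for treated clones and blue for the parental line and day 0 clones. Treated clone libraries lie between 5.27% and 10.8%, and parental and day 0 libraries between 0.521% and 2.58%.

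Added length was spread over bins with and without coverage elsewhere. For this comparison, chosen after the data were seen, all 25 kb bins were sorted by their coverage in libraries of the other experiment. Bins with no coverage in the dTAG parental line (78990 bins) were 1.24% ± 0.554 covered in the KO clones (SD, n = 4) and 0.0133% ± 0.00144 in the KO parental line (SD, n = 2), and made up 38.5% of the added length. Bins covered by more than 0% and under 5% (26018 bins) made up 47.1% of it (6.15% ± 1.75 against 1.58% ± 0.459). Bins at 5% to 20% (12789) were 13.2% ± 2.20 and 10.2% ± 3.00 covered, and bins at 20% or more (3394) 27.9% ± 2.91 and 28.6% ± 7.89. The differences were 1.23, 4.57, 3.00 and -0.645 percentage points, so the large share of the barest bins comes from their number. At day 21 and day 0 in the dTAG clones, sorted by the KO parental line, the means from the barest bins up were 1.51% and 0.0339%, 6.60% and 1.88%, 12.1% and 7.16%, and 25.3% and 22.0% (n = 4 each). The differences of these 4 steps (89534, 15897, 11912 and 3848 bins) were 1.47, 4.72, 4.93 and 3.33 percentage points, and they made up 47.4%, 26.9%, 21.1% and 4.60% of the added length. Exact two-sided permutation p was 0.0286, 0.0286, 0.0571 and 0.429 at day 21, which correction over 8 tests raised to 0.114, 0.114, 0.133 and 0.490, so none passed.

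**Figure D3:**
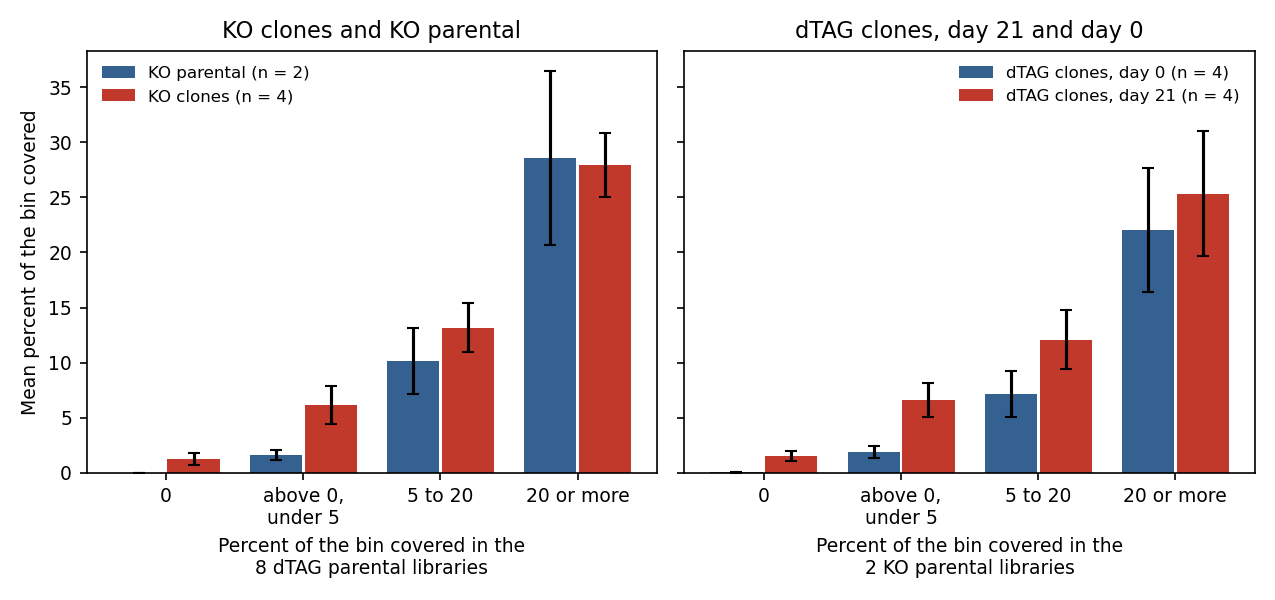
Mean percent of 25 kb bins covered (bars, with SD as error bars), for bins sorted by coverage in libraries of the other experiment, in KO clones and KO parental line and in dTAG clones at day 21 and day 0. In bins without coverage the means were 1.24% against 0.0133% and 1.51% against 0.0339%.

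Among the fixed gene groups, that of genes tied to t(4;14) or NSD2 was small. Of 7 tested members 5 were gained in the KO clones and none lost, also when adjusted over the list alone, and camera placed the list up (adjusted p = 0.0058). That call was lost with an estimated correlation (adjusted p = 0.957). TGFA, a ligand of the EGF receptor (chromosome 2, 70447284 to 70553826), went from 0.388% ± 0.0491 to 14.6% ± 3.84 (SD, n = 2 and 4; adjusted p = 0.00108), and MET, the receptor of hepatocyte growth factor (chromosome 7, 116672196 to 116798377), from 0.449% ± 0.0627 to 9.07% ± 2.89 (adjusted p = 0.000462). PAK1 (6.27 percentage points) and RRAS2 (4.16; named after its values were seen) also gained. At day 21 the count was 5 of 7 again, with TGFA at 14.6 percentage points, MET at 6.21, PAK1 at 5.19 and RRAS2 at 3.26 (camera adjusted p = 0.0567). After scaling 4 of 7 were gained and none lost in each comparison, while lists shortened to equal length left 0 in the KO clones and 3 at day 21.

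Developmental regulators, classical Polycomb targets, went both ways. Of 35 HOX genes 1 gained (HOXA3, 9.23 percentage points) and 1 lost (HOXD9, -28.4, although 6.74 with the lists shortened to equal length) in the KO clones, or 1 and 0 adjusted over the list alone. camera placed the HOX list down (adjusted p = 0.00905), a call lost with an estimated correlation (adjusted p = 0.957). At day 21, 3 HOX genes gained (HOXD13, 17.4, HOXD3, 9.05, and HOXA3, 8.15, or -2.54 when scaled) and 0 lost, also over the list alone, and scaling turned the HOX counts to 0 gained and 10 lost in the KO clones and 2 and 14 at day 21. Of 73 developmental transcription factors 10 gained and 5 lost in the KO clones (also over the list alone) and 12 gained and 2 lost at day 21 (3 and 2 over the list alone). Scaled counts were 4 and 14, and 4 and 23. FOXF1 fell by 25.0 percentage points (FOXF1 KO vs parental turned to 1.17 with peaks joined over gaps up to 3 kb) and FOXA2, a factor of liver and gut development, by 15.1 in the KO clones, while SOX21 rose by 31.5, EOMES by 12.7 and BARHL2 by 11.7 at day 21. SOX21 was at 9.23 after scaling (adjusted p = 0.611) and 17.3 with the pileup covariate (adjusted p = 0.32), and EOMES at 6.14 (adjusted p = 0.279) and 6.47 (adjusted p = 0.269). HOXD13 (6.70 and 13.5) also lost its call in both, and HOXD3 with the covariate (adjusted p = 0.0612). HOXA3 KO vs parental lost its call when scaled (1.35) and turned to -0.725 at a fold of at least 4, and HOXA3 dTAG clones day 21 vs day 0 turned there to -1.01.

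Most genes of other blood lineages were not called. Of all tested genes 18.0% were gained in the KO clones and 26.5% at day 21. B cell genes counted 5 gained and 0 lost of 27 in the KO clones (5 and 0 over the list alone) and 8 and 1 at day 21 (9 and 1). T and NK cell genes counted 4 and 0 of 23 (4 and 0), and 8 and 0 at day 21 (8 and 0). Myeloid genes counted 3 and 0 of 23 (3 and 0), and 8 and 0 at day 21 (8 and 0). Scaling turned these groups to 2 and 4, 2 and 8, and 1 and 7 in the KO clones, and to 3 and 9, 5 and 5, and 3 and 6 at day 21. camera placed none of these 3 lists up or down before scaling (adjusted p of 0.371 to 0.799). CD247, the T cell receptor zeta chain, gained 14.3 percentage points in the KO clones and 14.5 at day 21, and CD8A 12.7 and 17.5. BLNK and CR2, both of B cell receptor signalling, gained 10.2 each in the KO clones. CD14, a monocyte receptor of only 2 kb on chromosome 5 (140631732 to 140633701), went from 0% to 58.9% ± 24.2 at day 21 (SD, n = 4; adjusted p = 0.00493), and LYZ, the lysozyme gene, gained 15.6 in the KO clones. With the pileup covariate the day 21 change of CD247 was 7.50 (adjusted p = 0.0529). After scaling the calls of CD247 (3.60 and 3.52), and of CD8A (5.64) and CR2 (5.39) in the KO clones, were lost. At a fold of at least 4, CD8A KO vs parental turned to -2.33 and CR2 KO vs parental to -0.255. Among 19 plasma cell genes, which mark the cell of origin of myeloma, FCRL5 alone was called, with gains of 17.1 and 19.2 (1 and 0 over the list alone in each), and scaling gave 0 and 1, and 0 and 6, with FCRL5 at 7.58 (adjusted p = 0.169) and 7.23 (adjusted p = 0.0786).

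Cell adhesion, matrix and channel genes held gains and no losses before scaling, and camera placed none of their lists up or down (adjusted p of 0.0742 to 0.796). Other cadherins counted 6 gained and 0 lost of 19 in the KO clones (6 and 0 over the list alone) and 8 and 0 at day 21 (10 and 0). Collagens counted 9 and 0 of 34 (9 and 0) and 14 and 0 (14 and 0), potassium channels 6 and 0 of 65 (6 and 0) and 16 and 0 (15 and 0), and glutamate and GABA receptors 7 and 0 of 21 (7 and 0) and 8 and 0 (8 and 0). Neuronal genes counted 4 and 0 of 13 (5 and 0) and 5 and 0 (5 and 0), and epithelial and mesenchymal genes 8 and 0 of 24 (8 and 0) and 9 and 0 (10 and 0). GRIN2A, a glutamate receptor gene, is in 2 of these lists. Scaling brought losses into each of these groups, with 4 and 6, 8 and 15, 4 and 15, 7 and 7, 5 and 4, and 2 and 1 in the KO clones and 6 and 6, 12 and 17, 8 and 23, 7 and 11, 3 and 7, and 6 and 4 at day 21. COL6A6 gained 7.35 and 11.2 percentage points, CDH17, a cadherin of the gut, 9.08 and 9.17, and GABRR3 9.43 and 6.59.

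Large gene families held both gained and lost members. Of 89 olfactory receptors 19 gained and 3 lost in the KO clones (21 and 3 over the list alone) and 25 gained and 0 lost at day 21 (26 and 0). After scaling these were 18 and 9, and 24 and 9, and camera then placed the list up (adjusted p = 0.00346 and 0.000676), also with an estimated correlation (adjusted p = 0.0103 and 0.00332). OR5AU1 was 0% covered in the KO parental line and 59.8% ± 20.7 in the KO clones (SD, n = 4). Of 322 ZNF genes 17 gained and 8 lost in the KO clones (11 and 2 over the list alone) and 35 gained and 5 lost at day 21 (25 and 4). camera placed ZNF genes down relative to other genes (adjusted p = 5.08e-05 and 9.32e-05), although their mean changes were 0.173 and 1.02 percentage points. Both calls were lost with an estimated correlation (adjusted p = 0.957 and 0.912), and scaled counts were 11 and 47, and 18 and 154. Of 85 keratins and keratin-associated proteins 6 gained and 2 lost in the KO clones (2 and 0 over the list alone) and 11 and 0 at day 21 (6 and 0), or 4 and 15, and 7 and 23, after scaling. The 3 clustered protocadherins gave no call, with camera down in the KO clones (adjusted p = 0.0458, or 0.957 with an estimated correlation), and 0 and 3 when scaled there.

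Housekeeping and ribosomal protein genes were seldom called before scaling. Housekeeping genes counted 1 gained and 0 lost of 24 in the KO clones (EMC7, 1.39 percentage points; 1 and 0 over the list alone) and 2 and 0 at day 21 (EIF4A2, 11.3, and RPL4, 4.41; 2 and 0), or 0 and 0, and 1 and 10, after scaling. Of 72 ribosomal protein genes RPL15 gained 11.1 and RPL6 lost (-8.60) in the KO clones (0 and 0 over the list alone), and 6 gained at day 21 (1 and 0). Scaled counts were 0 and 3, and 1 and 10. camera placed that list down in the KO clones (adjusted p = 0.0425, or 0.957 with an estimated correlation), although its median change was 0.543. Antigen presentation and interferon genes counted 6 and 0 of 35 (5 and 0) and 9 and 0 (8 and 0), or 1 and 0, and 4 and 5, when scaled. HLA-DPA1 gained 15.4 and 13.0, and HLA-DPB1, which overlaps it, 13.9 at day 21, although both day 21 calls were lost with the pileup covariate. So were those of EIF4A2, RPL4, PHC1, PHC2 and WIF1 at day 21 and RNF2 in the KO clones, and scaling ended the KO calls of EMC7, RPL15, RNF2 and SFRP1. PRC2, PRC1 and NSD family genes counted 1 and 0 of 21 (RNF2; 0 and 0 over the list alone) and 2 and 0 (PHC1, and PHC2, which turned to -1.15 when scaled; 0 and 0), or 0 and 3, and 0 and 11, when scaled. Cell cycle inhibitors and tumour suppressors counted 2 and 0 of 16 (WIF1 and SFRP1; 2 and 0) and 1 and 0 (WIF1; 0 and 0), or 1 and 0, and 1 and 8, when scaled.

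Over the whole series, called H3K27me3 length was higher on average where NSD2 was labelled as lost. The 16 libraries of KO clones and treated dTAG clones had 119 Mb ± 24.2 called (SD, n = 16), against 62.2 Mb ± 18.9 in the 14 others (SD, n = 14). The ranges of 78.3 to 168 Mb and 36.1 to 99.8 Mb overlapped. For the called length NSD2-depleted vs NSD2-retaining in peaks at -log10 q of at least 5 the difference turned to -1.90 Mb (two-sided permutation p = 0.646), and at a fold of at least 4 it was 0.0683 Mb (two-sided permutation p = 0.949). Permutation within each experiment gave a two-sided p = 1e-05, the smallest that 100000 permutations can give (adjusted p = 6e-05 over 6 comparisons). Genes held 44.9% ± 0.997 and 51.9% ± 0.815 of that length, with no overlap between the ranges of 43.3% to 47.0% and 50.8% to 53.3%. The libraries also differed in depth, with a background pileup of 2.29 ± 0.368 and 1.79 ± 0.677 (two-sided permutation p = 0.0153, adjusted p = 0.0671 over 54 tests). The difference at -log10 q of at least 5 takes no account of this. Among replicate 1 libraries with a pileup of 1.81 to 2.58, that length was 17.7 to 28.2 Mb in the depleted ones. It was 27.7 to 36.4 Mb in the others. This range of pileup was chosen after the values were seen. Called length per unit of pileup was 51.7 Mb ± 4.28 and 35.6 Mb ± 3.25, with ranges of 45.7 to 60.3 and 30.3 to 40.5. This measure was chosen after the data were seen. Repeated libraries of a clone over time are not independent, so this p is too small for a statement on clones.

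**Figure D4:**
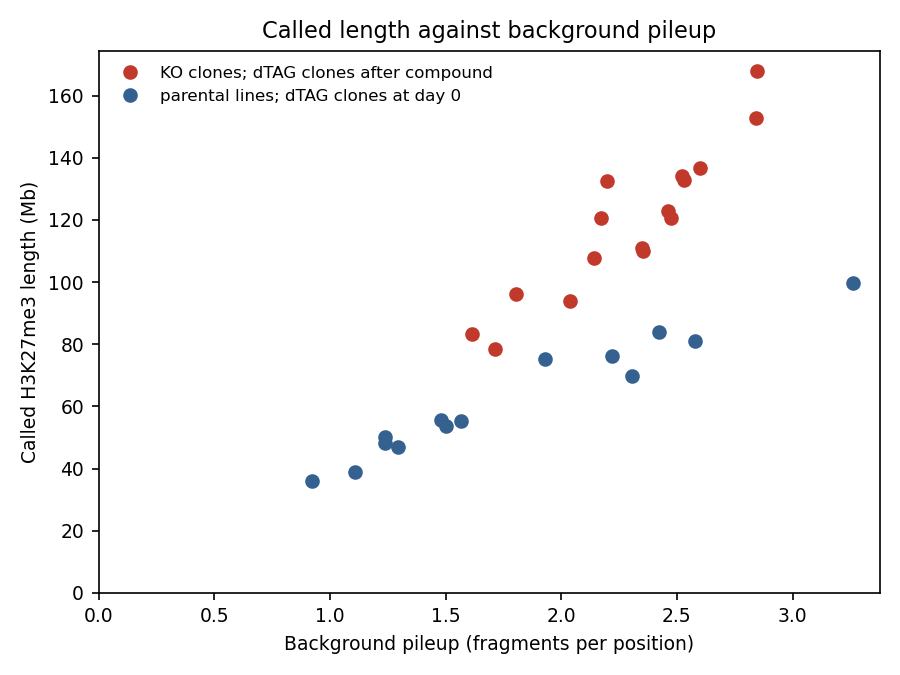
Called H3K27me3 length in Mb (vertical axis) against the estimated background pileup in fragments per position (horizontal axis) for the 30 libraries, red for KO clones and treated dTAG clones and blue for parental lines and day 0 clones. Called length per unit of pileup was at least 45.7 Mb in the red libraries and at most 40.5 Mb in the blue ones.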

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

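The predictions on weaker signal in covered bins and on depth between the KO clones were written before their tests, and those on depth of all libraries, on the compound and on the other splits of the libraries after the result was seen. Results below were listed because a test of the difference between 2 groups' changes passed in limma, and few of the named genes meet the fixed naming rule, so they were chosen after their values were seen.

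At day 7 the change in the dTAG clones exceeded that in the dTAG parental line in 5 genes, BPIFC (15.6 percentage points), FOLR2, a folate receptor of macrophages (38.8), ATP6V1G3 (8.73), DEFB132 (57.8) and GSDMC (8.27), and was lower in 0 (2013 at unadjusted p under 0.05 in limma). After scaling by called length 504 were higher and 752 lower, and with the pileup covariate 3 and 3. At day 14 it was higher in 92 genes and lower in 2, XBP1, the plasma cell transcription factor (-25.3; adjusted p = 0.0419), and SLBP, a histone mRNA binding protein gene near FGFR3 (-6.07; adjusted p = 0.0419). After scaling these counts were 795 and 1039, and with the covariate 206 and 65. At day 21 it was higher in 270 genes and lower in 12, or 673 and 771 after scaling. From day 7 to day 21 the clones gained 58 genes and lost 8. From day 7 to day 14 they gained 5, ZSWIM2 (9.71), CATSPER2 (4.79), COL5A2, a fibrillar collagen (2.24), IFTAP (3.20) and SMARCA1 (4.10), and lost 3, ATP6V1G3 (-6.15), C6orf15 (-77.0) and BPIFC (-5.46), or 21 and 2 after scaling. Clone 8 changed less than clone 11 in 1 gene at day 7, ATP6V1G3 (-12.7), and more in 2 genes at day 21, ZSWIM2 (6.57) and SPINT4 (33.9). KO clone 3 exceeded KO clone 12 in 540 genes and fell short of it in 13, or 56 and 6 after scaling by called length.

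The longer called length without NSD2 was weighed first. Depth, as far as the estimated pileup measures it, does not account for it alone, since the lowest depleted library had 45.7 Mb per unit of pileup and the highest other library 40.5. Treated dTAG parental libraries reached at most 39.0, below the lowest treated clone library. Their dose is not stated and each day had 2 libraries, so an effect of the compound in the clones is not excluded. In the dTAG clones, 1 of 35 splits of the 8 libraries called as many genes as the real split at day 7, 1 at day 14 and 1 at day 21, each time the real one. The other splits mix treated and day 0 libraries, whose called lengths did not overlap, so few calls in them were foreseeable. The splits therefore say nothing about the cause of the longer lists. Spread of H3K27me3 after NSD2 loss is the explanation that the design offers, but a change in signal over background, with 14.3% of peaks at -log10 q of at least 5 against 28.2%, was not tested and could also lengthen the lists.

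The lack of added length at -log10 q of at least 5 was weighed next. Lower depth by the same estimate does not account for it, since depleted libraries had a mean pileup of 2.29 against 1.79. Among replicate 1 libraries with a pileup of 1.81 to 2.58, depleted ones had 17.7 to 28.2 Mb at that threshold. The others had 27.7 to 36.4 Mb, so at like depth the length was mostly lower in these depleted libraries. Weaker signal in bins that the KO parental line covered by 20% or more stays open, since their coverage at that threshold changed by -2.20 percentage points from day 0 to day 21 (exact two-sided p = 0.571). That test took no account of the higher mean pileup at day 21 (2.33 against 1.44). A biological dilution of the mark from its strongest sites was not tested apart from this.

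The larger gain in KO clone 3 was weighed last. Depth stays open as a part of it, since 593 genes differed between the clones with pileup as covariate and 553 without, while the median difference over all genes was 0.473 percentage points with the covariate and 1.14 without. Scaling by called length left 56 higher and 6 lower, and the cause was not tested. No biological explanation was tested.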

How the results depend on the processing

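Alternatives that use background pileup were chosen after the data had been seen, and all others were fixed before. Of the 382 alternatives to the lengths, bin coverages and gene counts, 221 kept the direction and the side of the threshold (for counts, stayed within 1.5 times), 134 counts moved further, 20 values kept their direction with p over 0.05 and 7 turned. Of 3066 alternatives to single named genes 2185 kept their call, 838 kept their direction only and 43 turned, and of 29 for gene lists these were 12, 13 and 4. FGFR3, not called in either comparison, also turned when scaled and with the pileup covariate, but is not among the 43. Both peak overlaps moved when 50% reciprocal overlap was required. Stricter, joined and shortened lists hold less or other sequence by construction, and for all other changes the cause was not tested. Promoter windows were not run, because the gene annotation has no strand. Depth limits what a list can show, since weak regions drop out of shallow libraries.

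Lengths in Mb, by exact or permutation two-sided tests. With peaks at -log10 q of at least 5, the difference was -2.53 (called length KO vs parental, exact or permutation p = 0.867), 3.4 (called length dTAG clones day 7 vs day 0, exact or permutation p = 0.6), -1.32 (called length dTAG clones day 14 vs day 0, exact or permutation p = 0.829), 2.55 (called length dTAG clones day 21 vs day 0, exact or permutation p = 0.743), -1.9 (called length NSD2-depleted vs NSD2-retaining, exact or permutation p = 0.646). With a fold of at least 4, the difference was 1.47 (called length dTAG clones day 7 vs day 0, exact or permutation p = 0.4), -0.562 (called length dTAG clones day 14 vs day 0, exact or permutation p = 0.8), 0.115 (called length dTAG clones day 21 vs day 0, exact or permutation p = 1), 0.0683 (called length NSD2-depleted vs NSD2-retaining, exact or permutation p = 0.949). Per unit of background pileup, the difference was -0.595 (called length dTAG parental day 21 vs day 0, exact or permutation p = 1). The last of these is in Mb per unit of pileup.

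Gene counts are for genes gained KO vs parental and genes lost KO vs parental, genes gained dTAG clones day 7 vs day 0 and genes lost dTAG clones day 7 vs day 0, genes gained dTAG clones day 14 vs day 0 and genes lost dTAG clones day 14 vs day 0, genes gained dTAG clones day 21 vs day 0 and genes lost dTAG clones day 21 vs day 0, genes gained dTAG parental day 21 vs day 0 and genes lost dTAG parental day 21 vs day 0, genes gained day 21 clones minus parental and genes lost day 21 clones minus parental, in limma, higher first. With peaks at -log10 q of at least 5 they were 0 and 0 (KO vs parental), 9 and 1 (dTAG clones day 7 vs day 0), 5 and 5 (dTAG clones day 14 vs day 0), 28 and 9 (dTAG clones day 21 vs day 0), 0 and 0 (dTAG parental day 21 vs day 0), 1 and 2 (day 21 clones minus parental). With a fold of at least 4 they were 2 and 0 (KO vs parental), 25 and 12 (dTAG clones day 7 vs day 0), 9 and 9 (dTAG clones day 14 vs day 0), 23 and 14 (dTAG clones day 21 vs day 0), 1 and 0 (dTAG parental day 21 vs day 0), 0 and 2 (day 21 clones minus parental). With peaks joined over gaps up to 3 kb they were 1664 and 56 (KO vs parental), 1519 and 8 (dTAG clones day 7 vs day 0), 2036 and 41 (dTAG clones day 14 vs day 0), 2730 and 35 (dTAG clones day 21 vs day 0), 1 and 0 (day 21 clones minus parental). With lists shortened to equal total length they were 254 and 237 (KO vs parental), 249 and 273 (dTAG clones day 7 vs day 0), 456 and 525 (dTAG clones day 14 vs day 0), 550 and 527 (dTAG clones day 21 vs day 0), 0 and 5 (dTAG parental day 21 vs day 0), 25 and 22 (day 21 clones minus parental). Scaled by called length they were 1608 and 1893 (KO vs parental), 2023 and 4055 (dTAG clones day 7 vs day 0), 2257 and 4473 (dTAG clones day 14 vs day 0), 2250 and 4413 (dTAG clones day 21 vs day 0), 6 and 4 (dTAG parental day 21 vs day 0), 673 and 771 (day 21 clones minus parental). With an arcsine square root they were 904 and 23 (day 21 clones minus parental). Without the gene filter they were 7 and 0 (dTAG parental day 21 vs day 0). Without the trend they were 0 and 0 (dTAG parental day 21 vs day 0). With a change of at least 20 percentage points they were 103 and 23 (KO vs parental), 185 and 11 (dTAG clones day 7 vs day 0), 169 and 29 (dTAG clones day 14 vs day 0), 280 and 26 (dTAG clones day 21 vs day 0), 0 and 0 (dTAG parental day 21 vs day 0), 19 and 4 (day 21 clones minus parental). With only the compared groups in the fit they were 754 and 44 (KO vs parental), 0 and 0 (dTAG parental day 21 vs day 0). With background pileup as covariate they were 2390 and 391 (KO vs parental), 1331 and 353 (dTAG clones day 7 vs day 0), 1951 and 854 (dTAG clones day 14 vs day 0), 2053 and 712 (dTAG clones day 21 vs day 0), 2 and 1 (dTAG parental day 21 vs day 0), 411 and 111 (day 21 clones minus parental).

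Named genes that turned in the KO comparison, with the change in percentage points. With a fold of at least 4, ATG101 KO vs parental (5.96), BAIAP3 KO vs parental (3.19), CD8A KO vs parental (-2.33), CR2 KO vs parental (-0.255), ESRP1 KO vs parental (-0.496), FCRL1 KO vs parental (-0.139), HOXA3 KO vs parental (-0.725), RNF2 KO vs parental (-0.0876). With peaks at -log10 q of at least 5, CDH1 KO vs parental (-0.377), CR2 KO vs parental (-0.255), KRT6C KO vs parental (4.59), KRTAP10-1 KO vs parental (-25). With lists shortened to equal total length, CDH1 KO vs parental (-0.35), HOXD9 KO vs parental (6.74). With peaks joined over gaps up to 3 kb, FOXF1 KO vs parental (1.17).

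Named genes that turned in day 21 of the dTAG clones, with the change in percentage points. With peaks at -log10 q of at least 5, COL8A2 dTAG clones day 21 vs day 0 (-1.65), ISM2 dTAG clones day 21 vs day 0 (-1.06), KCNH2 dTAG clones day 21 vs day 0 (-1.36), KRT8 dTAG clones day 21 vs day 0 (-0.222), KRT84 dTAG clones day 21 vs day 0 (-3.05), LMO2 dTAG clones day 21 vs day 0 (-0.543), ZNF648 dTAG clones day 21 vs day 0 (-0.34). With lists shortened to equal total length, COL8A2 dTAG clones day 21 vs day 0 (-6.78), CSF3R dTAG clones day 21 vs day 0 (-3.87), ISM2 dTAG clones day 21 vs day 0 (-0.608), KCNH2 dTAG clones day 21 vs day 0 (-2.35), KRT8 dTAG clones day 21 vs day 0 (-1.1), KRT80 dTAG clones day 21 vs day 0 (-0.974), KRT84 dTAG clones day 21 vs day 0 (-8.21). Scaled by called length, CSF3R dTAG clones day 21 vs day 0 (-1.06), HOXA3 dTAG clones day 21 vs day 0 (-2.54), KCNH2 dTAG clones day 21 vs day 0 (-0.169), KCNJ10 dTAG clones day 21 vs day 0 (-2.02), KCNN3 dTAG clones day 21 vs day 0 (-11.6), LMO2 dTAG clones day 21 vs day 0 (-2.4), PHC2 dTAG clones day 21 vs day 0 (-1.15), RPL12 dTAG clones day 21 vs day 0 (-2.63), RPL27A dTAG clones day 21 vs day 0 (-3.25). With a fold of at least 4, FCRL3 dTAG clones day 21 vs day 0 (-1.45), HOXA3 dTAG clones day 21 vs day 0 (-1.01), KCNJ10 dTAG clones day 21 vs day 0 (-3.27), OCLN dTAG clones day 21 vs day 0 (-1.67), PHC2 dTAG clones day 21 vs day 0 (-0.507).

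The direction in fry was up, against down in camera, for gene list C2H2 zinc finger (ZNF) genes, KO vs parental (adjusted p = 0.786) and gene list C2H2 zinc finger (ZNF) genes, dTAG clones day 21 vs day 0 (0.177) and gene list ribosomal protein genes, KO vs parental (0.46). fry tests a list against no change and camera against other genes, so these 3 do not reverse the camera result, although the counts above hold them as turned. The ribosomal list turned to up in camera with lists shortened to equal length (adjusted p = 0.0676).

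Leaving out each library in turn gave, from lowest to highest, 49.4 to 76.7 (called length KO vs parental), 56.2 to 67.4 (called length dTAG clones day 7 vs day 0), 55.4 to 73.6 (called length dTAG clones day 14 vs day 0), 58.8 to 81.9 (called length dTAG clones day 21 vs day 0), -1.87 to 42.2 (called length dTAG parental day 21 vs day 0), 53.4 to 59.5 (called length NSD2-depleted vs NSD2-retaining), 6.74 to 8.46 (coverage of KO-gained bins in dTAG clones day 21 vs day 0), 0 to 64 (genes gained dTAG parental day 21 vs day 0), 0 to 6 (genes lost dTAG parental day 21 vs day 0), 5 to 848 (genes gained day 21 clones minus parental), 0 to 50 (genes lost day 21 clones minus parental), 1675 to 2877 (genes gained dTAG clones day 7 vs day 0), 16 to 64 (genes lost dTAG clones day 7 vs day 0), 1941 to 3499 (genes gained dTAG clones day 14 vs day 0), 58 to 148 (genes lost dTAG clones day 14 vs day 0), 2546 to 3968 (genes gained dTAG clones day 21 vs day 0), 39 to 117 (genes lost dTAG clones day 21 vs day 0), 1078 to 2679 (genes gained KO vs parental), 71 to 90 (genes lost KO vs parental). Where 1 library remained in a group, limma assumed that it varies like the other groups.

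Replicate numbers are shared by all groups, but were not taken to pair the libraries, because not every pair correlated at over 0.1 and no label gives a shared batch: deviations of same-numbered groups correlated in 105 pairs with r of 0.0335 to 0.558 (median 0.187), and 84 pairs were over 0.1. All 105 correlations were above 0 and replicate 1 had the higher pileup in 12 of 15 groups. Replicate 1 also had more peaks than replicate 2 in every group. Its shortest peak was 172 to 226 bp long, against 227 to 286 bp in replicate 2. Same-numbered replicates therefore share a difference, whose source no label gives, and tests without the block ignore it. With the replicate number as a block (replicate block), values were 61.1 (called length dTAG clones day 7 vs day 0; exact permutation p = 0.0556), 14.5 (called length dTAG clones day 7 vs day 0, per unit of pileup; exact permutation p = 0.0556), 62.1 (called length dTAG clones day 14 vs day 0; exact permutation p = 0.0556), 15.7 (called length dTAG clones day 14 vs day 0, per unit of pileup; exact permutation p = 0.0556), 69.6 (called length dTAG clones day 21 vs day 0; exact permutation p = 0.0556), 14.9 (called length dTAG clones day 21 vs day 0, per unit of pileup; exact permutation p = 0.0556), -0.595 (called length dTAG parental day 21 vs day 0, per unit of pileup; exact permutation p = 1), 7.57 (coverage of KO-gained bins in dTAG clones day 21 vs day 0; exact permutation p = 0.0556), where fewer permutations exist. The gene counts with the block that moved, for the same measures (genes gained KO vs parental and genes lost KO vs parental, genes gained dTAG clones day 7 vs day 0 and genes lost dTAG clones day 7 vs day 0, genes gained dTAG clones day 14 vs day 0 and genes lost dTAG clones day 14 vs day 0, genes gained dTAG clones day 21 vs day 0 and genes lost dTAG clones day 21 vs day 0, genes gained dTAG parental day 21 vs day 0 and genes lost dTAG parental day 21 vs day 0, genes gained day 21 clones minus parental and genes lost day 21 clones minus parental), were 3030 and 167 (KO vs parental), 3830 and 57 (dTAG clones day 7 vs day 0), 3821 and 163 (dTAG clones day 14 vs day 0), 4449 and 116 (dTAG clones day 21 vs day 0), 744 and 45 (day 21 clones minus parental), and with pileup as well 2691 and 381 (KO vs parental), 1800 and 234 (dTAG clones day 7 vs day 0), 2350 and 608 (dTAG clones day 14 vs day 0), 2457 and 463 (dTAG clones day 21 vs day 0), 3 and 1 (dTAG parental day 21 vs day 0), 661 and 155 (day 21 clones minus parental).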

Other observations

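No hypothesis was tested in this part, and its results were chosen after their values were seen. SLBP, which lies between 1692731 and 1712319 on chromosome 4, close to FGFR3, fell by 4.31 percentage points in the KO clones (adjusted p = 0.00207 in limma) and changed by -1.03 at day 21 (adjusted p = 0.335). XBP1 changed by -4.06 in the KO clones (adjusted p = 0.561) and 7.06 at day 21 (adjusted p = 0.0935).

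On chromosome 1, 16.9% of tested 25 kb bins before its largest peak-free stretch (125.075 to 143.275 Mb) were gained in the KO clones (421 of 2487), and 53.9% after it (1455 of 2700). Mean coverage before it was 9.27% in the KO parental line and 11.7% in the KO clones, and after it 4.63% and 11.8%. In the dTAG clones it was 7.07% at day 0 and 11.4% at day 21 before it, and 3.45% and 11.2% after it. CTSK, SLAMF8, TEX35, PGLYRP3 and LRRC52, all among the 10 largest gains in the KO clones, lie after this stretch. So do CD247 and FCRL5, so these gains may share a regional change.

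Single clones against their own controls gave 3054 gained and 94 lost genes for KO clone 3 (1567 and 1764 scaled), 624 and 27 for KO clone 12 (945 and 692), 2370 and 34 for dTAG clone 8 at day 21 (1478 and 2651), and 1185 and 13 for clone 11 (1370 and 2243), by limma. Before treatment the dTAG clones and dTAG parental line differed in 0 genes (471 at unadjusted p under 0.05 in limma), or 90 higher and 109 lower when scaled. The KO parental line was higher than the dTAG parental line in 8 genes and lower in 0, or 70 and 23 when scaled. Clone 8 and clone 11 differed in 0 genes in limma at day 14 (406 at unadjusted p under 0.05).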
